A study of Caenorhabditis elegans with 23 samples.

How the data were processed

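The series holds 23 libraries of Caenorhabditis elegans RNA in 10 groups, made by PAT-seq, a 3′-end method that reads into the poly(A) tail. Per the labels, sequencing run 1 held young adult whole worms: the wild-type strain N2, the gld-2(q497) mutant and the cpb-3(bt17) mutant, with 3 libraries each. Sequencing run 2 held gld-2 worms fed bacteria with a non-targeting control RNAi or with RNAi against parn-1, caf-1, panl-2, ccf-1 or ccr-4, with 2 libraries each, and 2 libraries of N2 embryos at the 1- to 2-cell stage. The titles spell the cpb-3 strain in another way, and cpb-3 was taken as meant. One protocol text names N2 worms for the RNAi experiment, while the labels of those libraries name the gld-2 strain; the labels were followed, and the levels of the gld-2 gene are given with the results. Groups were taken from the labels alone.

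The deposited tables hold, per gene row and library, raw read counts, the counts of reads that carry a poly(A) tail, and the mean poly(A) tail length in nucleotides (nt) of those tailed reads. The submitters' processing notes name Bowtie, Bowtie2 2.2.4 and the genome build ce10; the counting tool, the read filters and the method that measured the tails are not given in the sources used here. Coordinates are those of the deposited tables, in ce10. It was checked that tailed counts never exceeded the counts, and that tail length times tailed reads was whole within 0.01 in 100.0% of values, so each length is a mean over whole lengths. Lengths ran from 4 to 129 nt. The tables have 31753 rows, of which 19998 had any count and 3657 merge several overlapping genes. Reference tables of another build (WBcel235) were used for gene names only, and 29111 rows were matched by accession.

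Expression was tested with edgeR 4.0.16 in R 4.3.3: the quasi-likelihood test (robust), TMM scaling, the filterByExpr defaults and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 called changed. Log2 changes have standard errors (SE) from this fit. Gene levels are given as CPM on TMM-scaled library sizes of the same fit, as mean ± SD over libraries. Tail lengths were tested with limma 3.58.1 (eBayes with trend and robust) on untransformed lengths in nt. A length that rested on fewer than 5 tailed reads was treated as missing, and a gene needed a mean of at least 20 tailed reads and at least 2 values in each group compared. The 9 libraries of run 1 shared 1 fit per measure, the 12 RNAi libraries of run 2 another, and the embryo libraries were fitted with N2 alone (5 libraries). No covariate was used. In left-out fits where a group keeps 1 library, that library is assumed to vary like the others.

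Before the data were examined, the tests, 21 gene lists, the alternatives and the rule for named genes were fixed. The lists cover oocyte and maternal genes, eggshell, sperm, meiotic prophase, P granules, cytoplasmic poly(A) polymerases and their partners, deadenylases, decapping and decay, polarity and division of the early embryo, early zygotic genes, vitellogenins, intestine, muscle, cuticle collagens, neurons, somatic gonad, ribosomal proteins, histones, heat shock and stress, innate immunity, and mitochondrially encoded mRNAs. The last has no value, since 0 rows lie on the mitochondrial chromosome in these tables. Each list with at least 5 measured members was tested with limma's camera, which compares members with all other genes, at a preset inter-gene correlation of 0.01 on log2 CPM (prior count 2) or on tail lengths. The test was repeated with an estimated correlation, and p was adjusted over the lists of a comparison. Members were counted at the adjusted p over all genes and again adjusted over the list alone. Genes named in the text are the perturbed genes, then the 5 largest increases and decreases per measure for gld-2 vs N2, cpb-3 vs N2 and embryo vs N2 (3 for other comparisons). These had an adjusted p under 0.05, groups that did not overlap, a locus name of letters, hyphen and number and, for expression, at least 20 CPM in the higher group. Up to 4 members of each described list with the smallest adjusted p were also named. Chance alone separates 3 libraries from 3 others in 10% of genes.

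Total counts ran from 2.2 to 15.95 M per library (M, 1e6) and tailed counts from 1.18 to 13.27 M. The fits were tested on simulated data, drawn from the real means with 100 genes changed per size. The changed genes came only from rows with higher mean counts or tailed reads than the tests required. The shares found therefore do not cover genes of lower counts. For gld-2 vs N2, expression changes of 1 on the log2 scale were found in 67% of cases (9863 genes) and tail changes of 10 nt in 58% (7936 genes). For ccf-1 RNAi the shares were 8% (9731 genes) and 34% (6675 genes). Changes of 2 on the log2 scale and of 20 nt were found in 100% and 100% of cases for gld-2 vs N2, and in 76% and 96% for ccf-1 RNAi. For the embryo comparison they were 53% (8951 genes) and 47% (6442 genes), and 98% and 84% for the larger sizes. Of all genes called in the simulations, unchanged genes made up 2.9% (expression) and 7.1% (tails) for gld-2 vs N2, 2.3% and 5.8% for ccf-1 RNAi, and 8.5% and 3.7% for embryos, so 3 of these 6 shares lay above the nominal 5%. Camera called 0 of 20 unchanged simulated lists in each simulated comparison. The genes were simulated independently, so this cannot show how often camera calls unchanged lists of correlated genes. Floors cover counting error only, since PCR copies were not separated. The interval given for matched genes resampled genes and does not cover the spread between libraries. A gene with 0 counts in a group has no fold here; list medians were also taken with such genes at a floor of 3 counts over the group.

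Alternatives were RLE size factors, no count filter, DESeq2 1.42.0, other minimums of tailed reads (a mean of 50, or a mean of 5 together with single values from 1 tailed read), weights by tailed reads capped at 100, and tail lengths centred per library. Others were fits of only the compared groups, the replicate number as a block, each library left out in turn, and, for the embryos, subtraction of the run difference of gld-2 worms. Added after seeing the data were fits without the 3 ribosomal RNA rows, fits on one-gene rows only, and fits without cpb-3 replicate 3. Overlaps of the 2 mutants were set against 20 simulations of unchanged groups. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9. The gene caf-1 was not analysed here, because no row carries that name, and whether the label means a CCR4-NOT or a chromatin assembly subunit is not given.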

Results

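PAT-seq gave a read count and a mean poly(A) tail length for each gene row in 23 libraries of C. elegans. Run 1 held young adult whole worms of the wild-type strain N2, of gld-2 (a cytoplasmic poly(A) polymerase mutant) and of cpb-3 (a mutant of a CPEB-family RNA-binding protein), with 3 libraries each. Run 2 held gld-2 worms on a control RNAi or on RNAi labelled parn-1, caf-1, panl-2, ccf-1 or ccr-4, and N2 embryos at the 1- to 2-cell stage, with 2 libraries each. Total counts, in M (1e6), ran from 8.34 to 13.29 M in N2, 6.91 to 15.95 M in gld-2 and 4.18 to 15.6 M in cpb-3. In run 2 they were 2.2 and 8.61 M for control RNAi, 6.18 and 12.38 M for parn-1, 5.51 and 5.8 M for caf-1, and 5.48 and 12.53 M for panl-2. The remaining groups had 3.68 and 6.51 M for ccf-1, 8.82 and 10.54 M for ccr-4, and 3.27 and 3.55 M for embryos. The 3 ribosomal RNA rows took 3.8 to 34.8% of counts, most in cpb-3 replicate 3 (34.8%), which also had the lowest share of tailed reads in run 1 (71.3%). Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Gene values are mean ± SD (n = 3 in run 1, n = 2 in run 2), changes are ± SE and positions are in ce10. Adjusted p-values are from edgeR for expression and limma for tails.

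The perturbed genes were read first. The gld-2 gene (I: 6370031 to 6385086) fell by 1.51 ± 0.23 on the log2 scale in gld-2 worms, from 10.9 ± 0.562 to 3.70 ± 0.965 CPM (edgeR adjusted p = 0.00012), and cpb-3 worms had 11 ± 0.858 CPM. In the RNAi libraries of run 2 its group means lay between 2.56 and 5.25 CPM. The cpb-3 gene (I: 5789173 to 5791726) fell in both mutants, from 49.1 ± 2.42 CPM in N2 to 26.9 ± 3.97 in cpb-3 (log2 change -0.86, adjusted p = 0.0066) and 25.8 ± 2.78 in gld-2 (-0.92, adjusted p = 0.00067). The call in cpb-3 was lost without N2 replicate 3 (adjusted p = 0.053). Whether the counted 3′ ends lie outside the altered part of either gene is not given in the sources used here. The deadenylase genes panl-2 (III: 6963857 to 6968021; log2 change -1.03) and ccf-1 (III: 11919089 to 11920120; -0.93) also fell in gld-2 against N2, with adjusted p = 0.00062 and 0.0024.

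Of the 5 targets, caf-1 has no row and was not measured. None of the other 4 had fewer reads past the test in the libraries labelled with RNAi against it, and 3 had more reads. The ccr-4 gene (IV: 12361630 to 12370602) had 979 ± 110 CPM in the libraries labelled ccr-4 RNAi against 15.8 ± 14.7 in control RNAi. Of the other targets, parn-1 (V: 12692524 to 12695237) had 66.1 ± 31.5 against 13 ± 0.154, and panl-2 had 793 ± 919 against 16 ± 1.52. The edgeR adjusted p-values were 0.71, 0.31 and 0.14, and those of DESeq2 3.6e-05, 0.00019 and 1.3e-05. The ccf-1 gene, the catalytic deadenylase subunit of the CCR4-NOT complex, had 70.3 ± 4.98 CPM against 84.4 ± 13.6 (log2 change -0.27, edgeR adjusted p = 0.92). In the libraries labelled panl-2 RNAi the panl-2 reads had tails of 17.5 ± 8.03 nt against 34 ± 1.67 in control RNAi (limma adjusted p = 0.078). The counts cannot tell the mRNA of the worm from reads of the RNAi construct or of another library, so these values are read counts at the target and neither measure its expression nor show or exclude a knock-down. RNAi groups are named by their labels alone below.

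**Figure D1:**
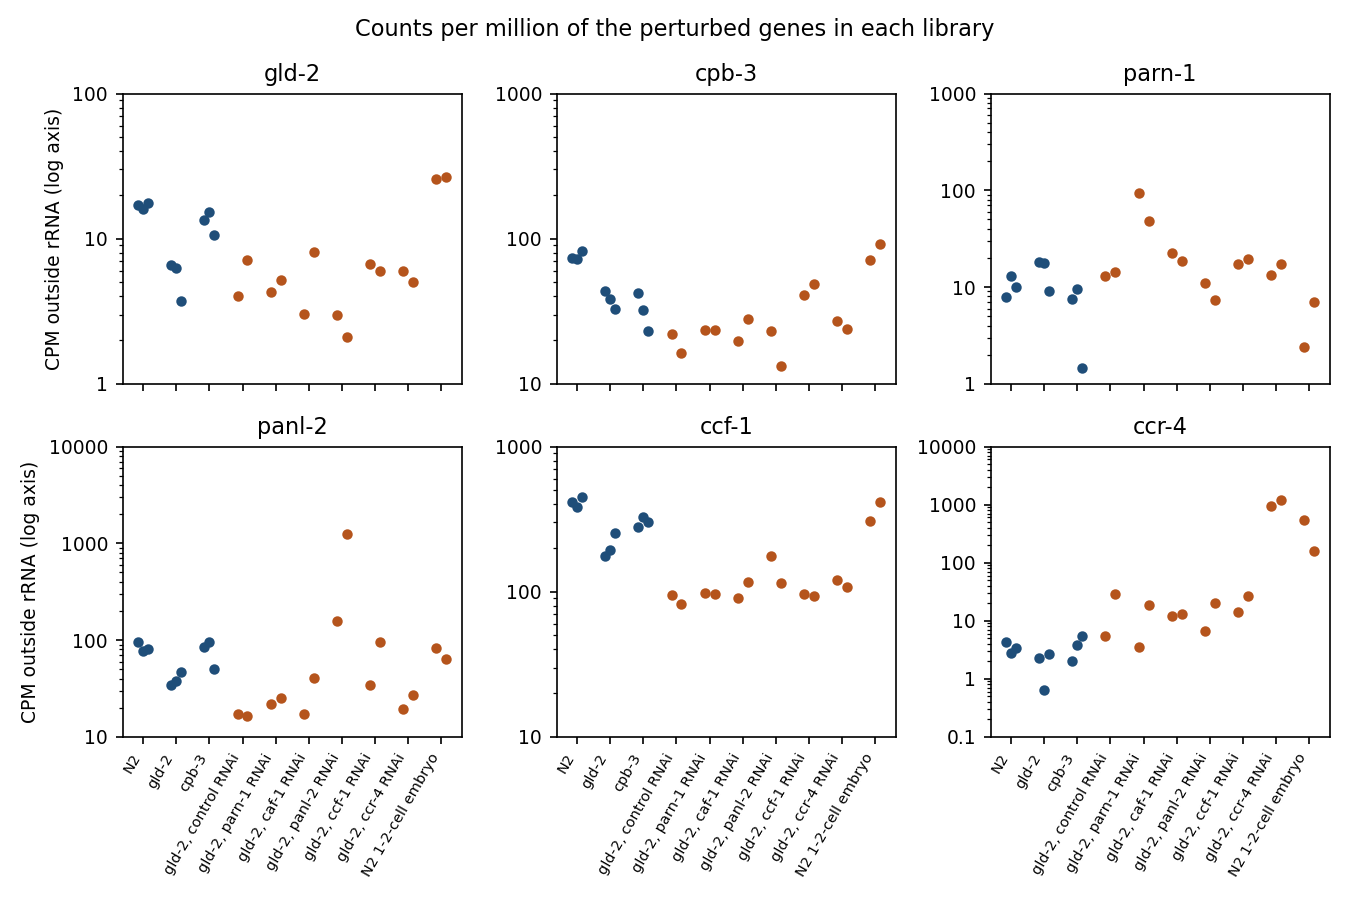
Reads of the 6 perturbed genes with a row, per library, as CPM of counts outside the ribosomal RNA rows (log axis; a different scaling from the edgeR CPM of the text). Points are libraries, run 1 in blue and run 2 in orange; ccr-4, panl-2 and parn-1 lie highest in the libraries labelled with RNAi against them, and ccr-4 is also high in the embryos.

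Median tail length per library, over genes measured in all libraries of a run, was 36.99 ± 1.10 nt in N2, 34.2 ± 2.07 in gld-2 and 37.96 ± 1.72 in cpb-3 (SD, n = 3). Exact two-sided permutation p-values were 0.2 for gld-2 vs N2, 0.4 for cpb-3 vs N2 and 0.2 for gld-2 vs cpb-3, where 0.1 is the smallest that 3 against 3 can give. In run 2 it was 32.84 ± 1.24 nt in control RNAi, 38.57 ± 0.55 in ccf-1 and 35.34 ± 1.72 in ccr-4. The others had 34.39 ± 1.41 in panl-2, 34.11 ± 2.02 in parn-1, 33.78 ± 1.92 in caf-1 and 35.2 ± 0.49 in embryos (SD, n = 2).

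**Figure D2:**
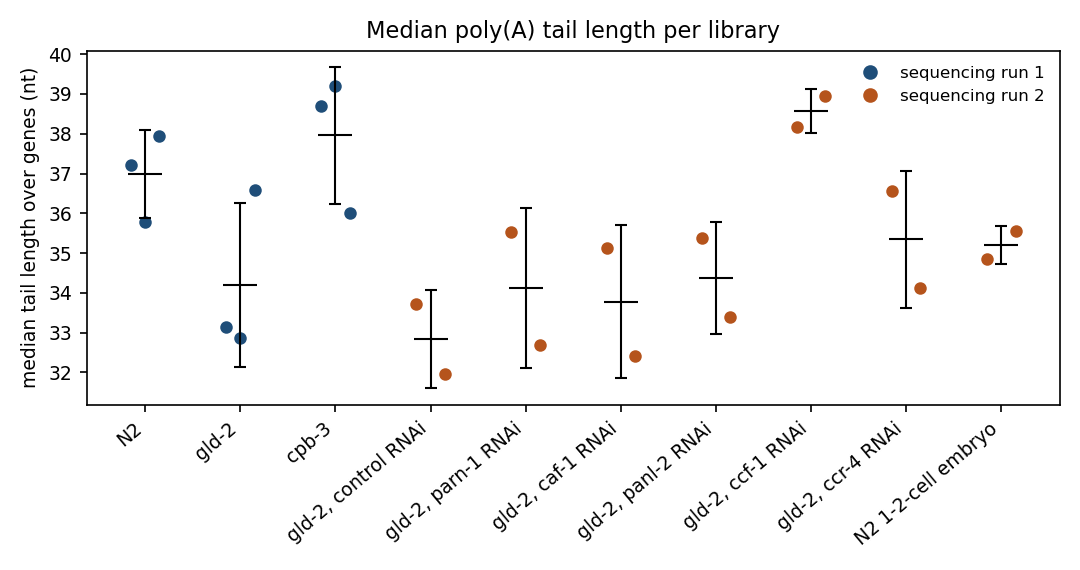
Median poly(A) tail length in nt of each of the 23 libraries (points), with the mean ± SD of each group and the runs in 2 colours. In run 2 both ccf-1 RNAi libraries, at 38.18 and 38.96 nt, lie above both control RNAi libraries, at 33.71 and 31.96 nt.

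The first comparison asked which mRNAs carry shorter tails in worms that lack the GLD-2 poly(A) polymerase. Maternal mRNAs of the oocyte had much shorter tails in gld-2 than in N2. The mRNA of mex-5 (IV: 13353706 to 13355519), an RNA-binding protein that polarises the zygote, went from 46.3 ± 1.24 to 26.2 ± 1.11 nt (change -20.12 ± 1.43 nt, limma adjusted p = 1.1e-05), and its relative mex-6 (II: 9524122 to 9525816) from 38.9 ± 1.17 to 20.7 ± 0.389 nt (adjusted p = 1.1e-05). The mRNAs of the PUF-family repressor puf-3 (IV: 13510494 to 13512121) and of the embryonic RNA-binding protein pos-1 (V: 8414074 to 8414920) changed by -16.72 ± 1.41 and -14.41 ± 1.34 nt. Of 24 measured oocyte and maternal genes, 19 were shorter, 0 longer and 5 not past the test (21 shorter adjusted over the list alone). Their median change was -10.04 nt (camera adjusted p = 8.9e-21; adjusted p = 0.049 with an estimated correlation).

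Eggshell mRNAs shortened as well, in 9 of 15 measured genes with 0 longer (12 adjusted over the list alone). Their median was -7.97 nt (camera adjusted p = 3.1e-08, adjusted p = 0.049 with an estimated correlation). The chitin-binding eggshell protein cbd-1 (IV: 11372972 to 11377347) went from 34.4 ± 1.73 to 20.2 ± 0.818 nt, the eggshell proteoglycan cpg-2 changed by -10.89 ± 1.20 nt, and the fertilisation receptor egg-1 by -10.97 ± 1.34 nt. Genes of polarity and division of the early embryo were shorter in 19 of 38 cases and longer in 0 (26 adjusted over the list alone). This list had a median of -6.41 nt (camera adjusted p = 6.1e-10, adjusted p = 0.24 with an estimated correlation). Among these, cyclin B gene cyb-3 (V: 15395696 to 15397050) changed by -12.67 ± 1.75 nt, cyclin E gene cye-1 (I: 6780822 to 6783881) by -10.16 ± 1.46 nt and the polo-like kinase plk-1 by -10.50 ± 1.82 nt. Sperm genes were shorter in 14 of 33 cases (22 adjusted over the list alone), with a median of -9.16 nt (camera adjusted p = 1.1e-08, adjusted p = 0.27 with an estimated correlation). The major sperm protein gene msp-33 went from 45.3 ± 3.98 to 22 ± 1.17 nt. The msp genes are near-identical copies, so reads may be split among them, and the single-gene values of this family are uncertain. The sperm list took 0.0206% of counts outside ribosomal RNA in N2 and 0.543% in gld-2. N2 tails of sperm genes thus rest on fewer reads. Such genes could pass the minimum of tailed reads mainly through the gld-2 libraries. Without N2 replicate 1 or 3 the shorter eggshell genes were 5 each, and the shorter genes of polarity and division 9 and 10, as they were 10 without gld-2 replicate 1 or 2.

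Somatic lists showed no such shift. Of 25 muscle genes 0 changed and the median change was 0.29 nt. Of 72 neuron genes 0 changed (median -1.28 nt), of 49 collagen genes 1 was shorter (median -0.12 nt) and of 28 intestine genes 1 was longer (median -0.44 nt). Camera placed muscle, intestine and collagen genes above other genes (adjusted p = 0.0064, 0.014 and 0.012; adjusted p = 0.83 for each with an estimated correlation). The medians of intestine and collagen genes were negative all the same. With single libraries left out the medians of muscle, intestine and collagen genes took both signs, from -1.14 (muscle) and -1.94 (intestine) without gld-2 replicate 3 to 1.15 and 0.40 without gld-2 replicate 2. Ribosomal protein genes had a median of -2.50 nt with 2 of 57 shorter (camera adjusted p = 0.012; adjusted p = 0.83 with an estimated correlation), and that median was 0.22 nt on centred tail lengths.

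**Figure D3:**
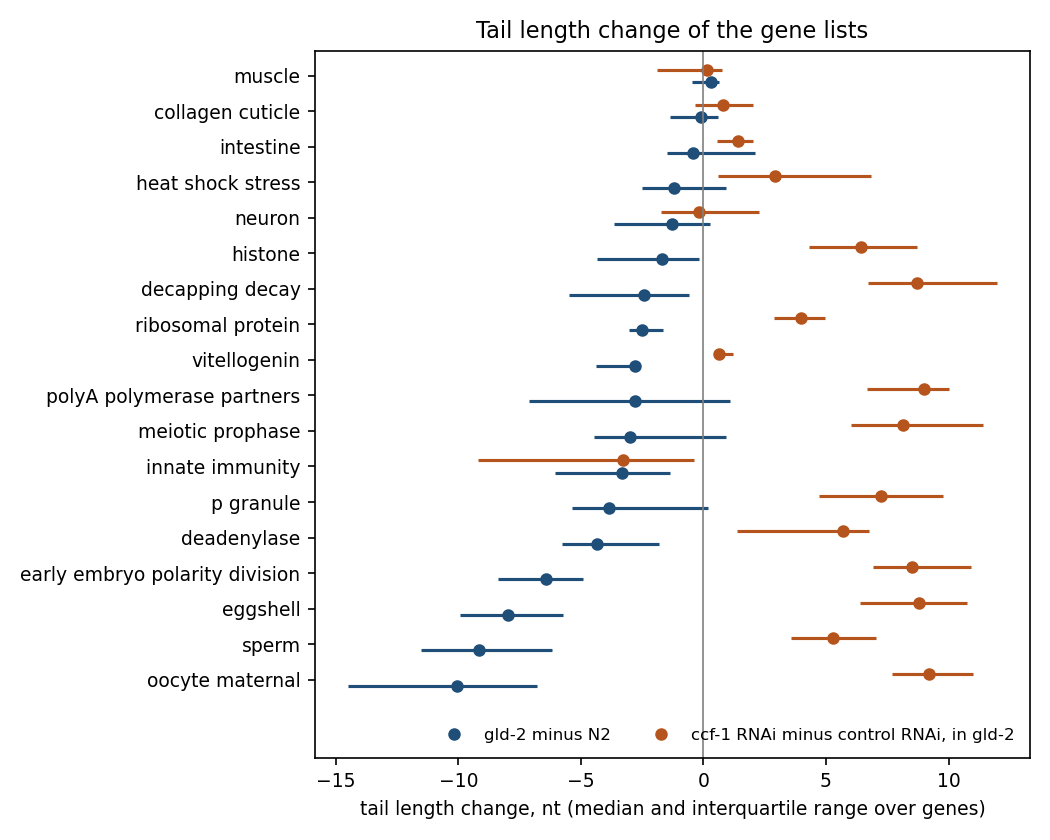
Change of mean tail length in nt for each gene list in gld-2 minus N2 and in ccf-1 RNAi minus control RNAi within gld-2; points are list medians and bars the interquartile range over genes. Oocyte and maternal genes sit at -10.04 nt in gld-2 minus N2 and at 9.22 nt in ccf-1 RNAi minus control RNAi; neuron genes sit at -1.28 and -0.18 nt.

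Over 7958 genes tested, limma called 891 shorter and 14 longer in gld-2 than in N2, and the median change of all genes was -2.22 nt. The largest decreases were those of the PDZ-domain gene gipc-1 (III: 4870804 to 4871978; -33.84 ± 4.09 nt), spch-1 (-31.05 nt), nspd-2 (-30.73 nt), irld-1 (-25.60 nt) and nspd-1 (-24.96 nt). The spch and nspd genes have near-identical copies. The counts of spch-1 were also far higher in gld-2, so its N2 tail rests on fewer reads. The largest increases were sedl-1 (16.68 nt), zip-8 (16.60 nt), ppw-2 (8.89 nt), fat-6 (5.41 nt) and rmo-1 (5.07 nt). Each of these 5 lost its call when some single library was left out, with zip-8 at 10.86 nt without gld-2 replicate 1. Centred, fat-6 and rmo-1 were at 8.13 and 7.79 nt. On tail lengths centred per library, 190 genes were longer and 589 shorter. The count of 905 was 498 without N2 replicate 1, 461 without N2 replicate 3, 497 without gld-2 replicate 1 and 515 without gld-2 replicate 2. The tail of irld-1 was not called without N2 replicate 1 (adjusted p = 0.053), nor that of spch-1 with the lower minimum of tailed reads (-21.96 nt, adjusted p = 0.095), which admits an N2 value from 4 reads.

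In expression, sperm genes were far higher in gld-2 than in N2. Of 44 measured sperm genes 39 rose, 0 fell and 5 did not pass (41 up and 1 down adjusted over the list alone). The median log2 change was 4.71 (camera adjusted p = 1.2e-29; adjusted p = 0.08 with an estimated correlation). The sperm-specific gene ssp-16 (I: 6102069 to 6102398) rose from 1.05 ± 0.344 to 86.4 ± 9.15 CPM (log2 change 6.40 ± 0.31, edgeR adjusted p = 8.2e-10). So did msd-4 (III: 4868378 to 4868707), with a major sperm protein domain, from 3.08 ± 0.721 to 144 ± 6.67 CPM and msp-59 (IV: 5312720 to 5313103) from 8.02 ± 1.06 to 323 ± 17.8 CPM. The list took 0.0206% of counts outside ribosomal RNA in N2, 0.543% in gld-2 and 0.173% in cpb-3. In gld-2 worms of run 2 on control RNAi it took 0.0487%.

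Oocyte, eggshell and early zygotic genes were lower in gld-2. Of 25 oocyte and maternal genes 17 fell and 0 rose (18 adjusted over the list alone). The list median was -0.79 (camera adjusted p = 8.8e-08, adjusted p = 0.08 with an estimated correlation). The oocyte maturation factor oma-2 (V: 8029489 to 8030900) fell from 419 ± 31.3 to 118 ± 10.3 CPM, the germline translational repressor gld-1 (I: 7695692 to 7697406) from 464 ± 37.1 to 127 ± 14.5 CPM. The nanos homologue nos-2 (II: 7065632 to 7066603) had a log2 change of -2.13 ± 0.20. Of 15 eggshell genes 9 fell and 0 rose (10 adjusted over the list alone), among them the chitin synthase chs-1 (I: 7554997 to 7559452; -1.78 ± 0.20). Their median was -1.06 (camera adjusted p = 0.00016, adjusted p = 0.22 with an estimated correlation). Of 15 early zygotic genes 13 fell and 0 rose (13 adjusted over the list alone), with a median of -2.61 (camera adjusted p = 8.8e-08, adjusted p = 0.018 with an estimated correlation). The embryonic homeobox gene ceh-51 (V: 18874104 to 18875878) fell from 7.85 ± 1.29 to 0.242 ± 0.167 CPM and the T-box gene tbx-9 (III: 10339971 to 10341757) from 13.1 ± 0.464 to 1.82 ± 0.283 CPM. The early zygotic gene pes-10 had 63 counts over the N2 libraries and 0 over the gld-2 libraries.

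Genes of polarity and division fell in 13 of 38 cases and rose in 3 (16 and 5 adjusted over the list alone). Here the median was -0.35 (camera adjusted p = 0.0049, adjusted p = 0.32 with an estimated correlation), and the cell-cycle phosphatase cdc-25.1 (I: 6469814 to 6471904) changed by -1.78 ± 0.18. Among 19 genes of poly(A) polymerases and partners 9 fell and 2 rose (9 and 2 adjusted over the list alone). Their median was -0.53 and their mean -0.16 (camera adjusted p = 0.017, adjusted p = 0.12 with an estimated correlation). The 2 that rose are CPEB-family genes. The gene fog-1 (I: 3211060 to 3217023), which specifies sperm fate, went from 20.7 ± 2.71 to 56.9 ± 4.1 CPM, and cpb-2 had 306 counts in gld-2 and 0 in N2. Ribosomal protein genes rose in 7 of 57 cases (5 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 0.00019, adjusted p = 0.67 with an estimated correlation). Other lists were not called by camera. These were meiotic prophase (0 up and 3 down of 27, median -0.02), P granules (4 and 5 of 21; median 0.12, mean -0.12), deadenylases (0 and 3 of 12, median -0.12), decapping and decay (0 and 4 of 11, median -0.08) and vitellogenins (0 and 1 of 5, median -0.19). The same held for intestine (1 and 6 of 31, median -0.16), muscle (0 and 2 of 25, median -0.13), collagens (9 and 9 of 70, median -0.15), and neurons (7 and 2 of 92, median 0.00). It also held for somatic gonad (0 and 2 of 10, median -0.06), histones (13 and 7 of 33, median 0.61), heat shock (4 and 1 of 15, median 0.31) and innate immunity (3 and 1 of 10, median 0.49).

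**Figure D4:**
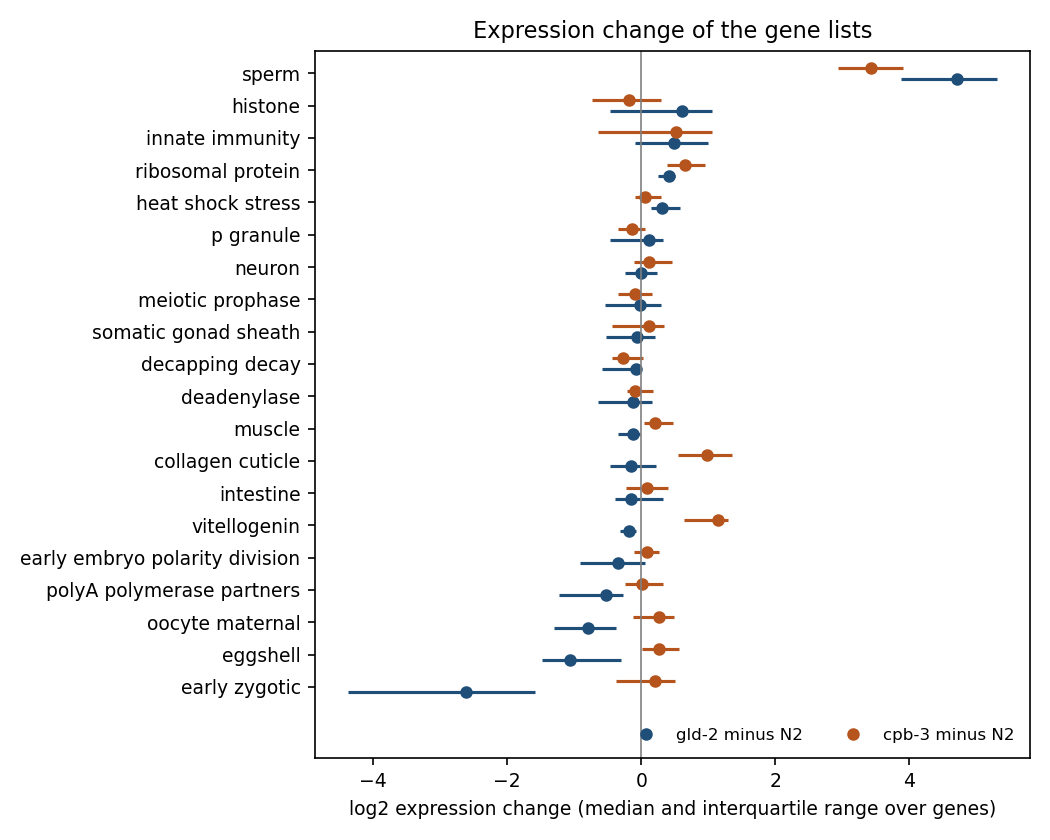
Log2 change of expression for each gene list in gld-2 minus N2 and in cpb-3 minus N2; points are list medians and bars the interquartile range over genes. Sperm genes have the highest median in both (4.71 and 3.43), and early zygotic genes the lowest in gld-2 (-2.61).

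Over 10357 genes edgeR called 1400 higher and 1548 lower in gld-2 than in N2, and DESeq2 called 3059 in all. The largest increases were the adenine nucleotide translocator ant-1.3 (39.1 ± 1.91 against 0.117 ± 0.149 CPM; log2 change 8.29) and the kinase kin-24 (25.6 ± 1.31 against 0.111 ± 0.0197 CPM; 7.69). They were followed by the sperm chromatin genes spch-3 (7.52 ± 0.40) and spch-1 (7.28 ± 0.31) and a further translocator, ant-1.4 (IV: 8459214 to 8460264; 42 ± 5.78 against 0.294 ± 0.294 CPM; 7.28). The largest decreases were the SKP1-related genes skr-8 (-6.30 ± 0.35), skr-7 (-5.78 ± 0.25) and skr-14 (-5.76 ± 0.34), the chitinase cht-1 (X: 3397785 to 3400002; -5.61 ± 0.35) and the caveolin cav-1 (IV: 9771134 to 9773344; -5.58 ± 0.23). The spch and skr genes have near-identical copies and are uncertain one by one. Across 7958 genes, which are not independent replicates, tail change and expression change had Pearson r = -0.12 and Spearman rho = -0.02. Among them 250 genes were shorter and lower, where independent lists of these sizes would share 138.4, and 88 were shorter and higher (82.7).

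The comparison of cpb-3 with N2 asked the same of the CPEB-family protein. Sperm genes were again higher: 37 of 44 rose, 0 fell and 7 did not pass (41 up adjusted over the list alone). The median log2 change was 3.43, or 3.40 with a gene at 0 counts set to its bound (camera adjusted p = 9e-45, adjusted p = 0.093 with an estimated correlation). The gene msp-59 went from 8.02 ± 1.06 to 70.5 ± 16.6 CPM (3.12 ± 0.21, adjusted p = 3.7e-07) and msp-76 from 9.31 ± 1.72 to 116 ± 29 CPM. The 5 largest increases were msp-57 (4.35 ± 0.33), msp-65, msp-40, cylc-2 (I: 9526607 to 9527371; 27.7 ± 21.7 against 1.31 ± 0.443 CPM) and msp-33 (4.12 ± 0.36). Oocyte and maternal genes had a median of 0.27 (2 up and 1 down of 25), eggshell genes of 0.26 (3 up of 15) and early zygotic genes of 0.21 (0 changed of 15).

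Cuticle collagens rose in 31 of 70 cases and fell in 1 (48 and 2 adjusted over the list alone), for example col-139 (V: 4652896 to 4653944) by 1.78 ± 0.29. Their median was 0.98 (camera adjusted p = 4.5e-12, adjusted p = 0.59 with an estimated correlation). Ribosomal protein genes rose in 21 of 57 cases (37 up and 1 down adjusted over the list alone), with rpl-33 at 2130 ± 1600 CPM against 484 ± 50.4. Here the median was 0.65 (camera adjusted p = 1.1e-10, adjusted p = 0.59 with an estimated correlation). Of 5 vitellogenins, the yolk protein genes of the adult intestine, 3 rose (4 adjusted over the list alone), with a median of 1.14 (camera adjusted p = 0.024, adjusted p = 0.59 with an estimated correlation). The yolk gene vit-6 (IV: 8261159 to 8266353) went from 3390 ± 765 to 9350 ± 5330 CPM (adjusted p = 0.0079). The calls of vit-4 and vit-5 were lost without N2 replicate 2 or 3 (adjusted p up to 0.088 and 0.11) and in a fit of only these 2 groups (0.062 and 0.084). Replicate 3 of cpb-3 had the highest share of counts on ribosomal protein genes (24.4% against 19.5 and 18.8%), collagens (10.3% against 8.02 and 7.8%) and vitellogenins (5.77% against 4.06 and 4.47%). Without it the medians were 0.31, 0.62 and 0.68, with 21, 26 and 3 genes up, and the changes of rpl-33 and vit-6 were 1.35 and 0.89. Without N2 replicate 2 the genes up were 5, 19 and 1, and without N2 replicate 3 they were 3, 12 and 1.

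The largest decrease was that of the germline nuclear Argonaute hrde-1 (III: 4172743 to 4176127), from 233 ± 15.9 to 82.2 ± 22.7 CPM (-1.49 ± 0.20, adjusted p = 0.00019). It was followed by nssp-46 (-1.31), col-158 (-1.05), chp-1 (-0.94) and the acid phosphatase acp-6 (-0.94). The call of col-158 was lost without each N2 replicate (adjusted p up to 0.084) and that of chp-1 without N2 replicate 3 or cpb-3 replicate 2 (up to 0.066).

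Over 10357 genes edgeR called 734 higher and 175 lower in cpb-3, and DESeq2 1195 in all. The count of 909 was 483 without N2 replicate 2, 380 without N2 replicate 3 and 455 with only these 2 groups in the fit. No tail length passed the test in cpb-3: limma called 0 of 7991 genes, with 762 at an unadjusted p under 0.05. On centred tail lengths 22 genes were longer and 48 shorter, and 4 genes passed without cpb-3 replicate 3. The tail of mex-5 was 48.2 ± 2.1 nt against 46.3 ± 1.24 in N2 (change 1.94, adjusted p = 0.73). Camera placed sperm genes (median -3.92 nt, 0 of 33 called, 7 shorter adjusted over the list alone, adjusted p = 9.4e-11) and ribosomal protein genes (median -2.83 nt, 0 of 57 called, 11 shorter adjusted over the list alone, adjusted p = 3.7e-33) below other genes. Both had adjusted p = 0.29 with an estimated correlation, and without cpb-3 replicate 3 their medians were -1.51 and -1.56 nt. Sperm genes had far lower counts in N2 than in cpb-3, so their N2 tails rest on fewer reads.

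The changes of both mutants against the same N2 libraries were then set side by side. Of genes tested in both, 366 were higher in both mutants, where independent lists would share 99.2, and 33 of the 366 are in the sperm list. Another 54 were lower in both (26.2) and 59 went opposite ways. Across genes, Pearson's r of the log2 changes was 0.59, against 0.48 in simulations of unchanged groups with the same controls. The covariance was 0.977 against 0.0494 simulated, while only 56.7% of genes changed in the same direction, against 66.1% simulated. For tail lengths r was 0.31 (0.48 simulated), the covariance 7.09 (6.94 simulated), the share with the same direction 52.1% (66.5% simulated), and 0 genes were shorter in both, since none was called in cpb-3. The simulated libraries had no shift shared by their genes, unlike the real ones, so these shares are not like for like. On centred tail lengths the share with the same direction was 57.7% (66.4% simulated). The 3 control libraries were not split, since 1 part would hold a single library, so part of the excess may come from sharing them.

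The direct comparison of gld-2 with cpb-3 subtracts no N2 value, but the N2 libraries share its fit and so its scaling, spread and p-values. Oocyte mRNAs again had shorter tails in gld-2: mex-5 had 26.2 ± 1.11 against 48.2 ± 2.1 nt (-22.06 ± 1.42, adjusted p = 4.3e-06). The oocyte maturation factor oma-1 (IV: 8889073 to 8890519) had 26.7 ± 0.132 against 43.3 ± 2.53 nt. Of 24 oocyte and maternal genes 20 were shorter and 0 longer (median -9.36 nt, camera adjusted p = 1.8e-13, adjusted p = 0.2 with an estimated correlation). Eggshell genes were shorter in 12 of 15 cases (13 adjusted over the list alone; median -9.47 nt, camera adjusted p = 1e-06, adjusted p = 0.2 with an estimated correlation). Genes of polarity and division were shorter in 27 of 38 cases (32 adjusted over the list alone), including cyb-3 (-13.33 ± 1.75 nt). Their median was -7.96 nt (camera adjusted p = 1.6e-08, adjusted p = 0.36 with an estimated correlation). The largest decreases were msrp-3 (-32.02 nt), kin-24 (-31.87 nt) and tag-89 (-31.57 nt). Largest among the increases were pqbp-1.2 (17.55 nt), rcs-1 (16.71 nt) and the sperm-specific family gene ssp-37 (16.01 nt). Without single libraries the calls of pqbp-1.2 (gld-2 replicate 1, 2 or 3 or cpb-3 replicate 3; adjusted p up to 0.12) and rcs-1 (gld-2 replicate 2; 0.051) were lost, as was that of pqbp-1.2 in a fit of only these 2 groups (0.084). With the lower minimum of tailed reads tag-89, where this admits a cpb-3 value from 4 reads, was at -14.52 nt and not called (0.48). The change of msrp-3 was then -48.34 nt. That of pqbp-1.2 was 10.24 nt without cpb-3 replicate 3 and 10.48 nt when weighted by tailed reads. Limma called 30 genes longer and 1513 shorter of 8039 (488 and 749 centred). The count of 1543 was 837 without gld-2 replicate 1 and 917 without gld-2 replicate 2. The shorter genes of polarity and division were then 15 and 14, and the shorter eggshell genes 7 without gld-2 replicate 2.

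In expression, sperm genes were higher in gld-2 than in cpb-3 for 31 of 44 genes and lower for 6 (median 1.44, camera adjusted p = 8.7e-06, adjusted p = 0.47 with an estimated correlation). The sperm phosphatase gene gsp-3 (I: 4709357 to 4710422) had 44.7 ± 6 against 2.55 ± 0.617 CPM. Oocyte genes fell in 19 of 25 cases (median -1.03, camera adjusted p = 2.2e-07, adjusted p = 0.11 with an estimated correlation), such as the germline fate factor pie-1 (III: 12426792 to 12428986; 27.8 ± 6.17 against 198 ± 58.3 CPM). Early zygotic genes fell in 12 of 15 cases (median -2.36, camera adjusted p = 6e-07, adjusted p = 0.024 with an estimated correlation). Collagens fell in 43 of 70 cases and rose in 4 (45 and 4 adjusted over the list alone; median -1.03, camera adjusted p = 6e-07, adjusted p = 0.47 with an estimated correlation). All 5 vitellogenins fell (median -1.23, camera adjusted p = 0.011, adjusted p = 0.25 with an estimated correlation), among them vit-2 from 10100 ± 2370 CPM in cpb-3 to 5250 ± 753. Without cpb-3 replicate 3 the medians of collagens and vitellogenins were -0.67 and -0.81. Over 10357 genes 1756 were higher and 2010 lower in gld-2 (DESeq2 3900 in all). The largest increases were ant-1.4 (6.72), ant-1.3 (5.75) and the histone H3 variant his-70 (4.89). The largest decreases were skr-9 (-8.76, 0.0546 ± 0.0946 against 37.1 ± 18.5 CPM), skr-8 (-6.45) and skr-7 (-6.13).

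The RNAi comparisons asked whether tails in gld-2 worms lengthen under each RNAi label, against control RNAi. The names parn-1, panl-2, ccf-1 and ccr-4 are those of deadenylase genes. Whether caf-1 means a CCR4-NOT or a chromatin assembly subunit is not given, so its values are not read as those of a deadenylase. In the libraries labelled ccf-1 RNAi the same kinds of germline mRNA carried longer tails. The mRNA of puf-3 had 35.2 ± 2.29 against 21.9 ± 1.03 nt (13.25 ± 1.95, limma adjusted p = 0.0033). The values were 38.4 ± 3.07 against 25.3 ± 0.656 nt for oma-1 (adjusted p = 0.0033) and 39.1 ± 5 against 25.4 ± 0.421 nt for mex-5 (adjusted p = 0.0044). Of 24 oocyte and maternal genes 21 were longer and 0 shorter (22 adjusted over the list alone). Their median change was 9.22 nt (camera adjusted p = 8.1e-09, adjusted p = 0.089 with an estimated correlation). Eggshell genes were longer in 8 of 15 cases (9 adjusted over the list alone), for example cpg-2 by 8.80 ± 1.67 nt. The list median was 8.80 nt (camera adjusted p = 0.00081, adjusted p = 0.24 with an estimated correlation). Genes of polarity and division were longer in 21 of 36 (29 adjusted over the list alone), among them cye-1 by 10.94 ± 1.86 nt and cdk-1, the mitotic kinase, by 8.78 ± 1.85 nt. Here the median was 8.50 nt (camera adjusted p = 1e-05, adjusted p = 0.24 with an estimated correlation). Poly(A) polymerase partners were longer in 7 of 15 (10 adjusted over the list alone; median 9.02 nt, camera adjusted p = 0.011, adjusted p = 0.089 with an estimated correlation). Without ccf-1 replicate 2, 0 members of these 4 lists were called, and without control replicate 2 they were 2, 0, 1 and 0. The oocyte genes called were 12 without control replicate 1 and the partner genes 4, while polarity and division genes were 14 without ccf-1 replicate 1. Medians of the 4 lists stayed between 6.92 and 10.99 nt in these fits.

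Lists of somatic tissues stayed behind. Of 54 neuron genes 0 changed and the median was -0.18 nt (camera adjusted p = 2.6e-08; adjusted p = 0.00025 with an estimated correlation). The synaptic gene unc-18 was at 7.21 ± 3.43 nt and the neuropeptide gene flp-5 at -10.19 ± 5.10 nt (adjusted p = 0.15 and 0.17). Of 24 muscle genes 0 changed (median 0.16 nt, mean -0.31, camera adjusted p = 2.6e-05, adjusted p = 0.19 with an estimated correlation). The tail of unc-15, paramyosin, was 35.7 ± 1.04 against 37.6 ± 0.292 nt (adjusted p = 0.52). Camera also placed collagens (median 0.78 nt, 1 of 40 longer, adjusted p = 0.00043), intestine genes (1.39 nt, 0 of 24, adjusted p = 0.039) and innate immunity genes (-3.28 nt, 1 of 7 shorter, adjusted p = 0.00017) below other genes. With an estimated correlation these had adjusted p = 0.39, 0.52 and 0.056. With single libraries left out the medians of neuron (-0.36 to 0.76 nt), muscle (-0.51 to 0.42) and collagen genes (-0.76 to 1.87) took both signs, each below the medians of the germline lists.

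Limma called 1332 genes longer and 13 shorter of 6678 in ccf-1 RNAi, and the median change of all genes was 5.31 nt. The largest increases were the tRNA methyltransferase trm-1 (26.95 ± 6.00 nt), prx-12 (25.89 nt) and adm-4 (25.86 nt). Among the decreases the largest were those of kreg-1 (-21 ± 7.22 nt; adjusted p = 0.05 after rounding, just past the test), hmg-11 (-15.43 nt) and cnc-4 (-13.52 nt). On centred tail lengths, which remove a shift shared by all genes, 9 genes were longer and 6 shorter. The count of 1345 was 0 without ccf-1 replicate 2, 30 without control replicate 2 and 893 without ccf-1 replicate 1. Each gene named as longer or shorter lost its call without ccf-1 replicate 2 (puf-3 and oma-1 with adjusted p = 0.061, mex-5 with 0.067), and each except hmg-11 lost it with centred tail lengths (puf-3 at 7.94 nt, oma-1 at 7.72 nt and mex-5 at 8.43 nt). Without control replicate 2 cnc-4 was at -6.94 nt and kreg-1 at -6.83 nt, while kreg-1 was at -35.17 nt without control replicate 1. Weighted by tailed reads, cnc-4 was at -8.47 nt and kreg-1 at -8.99 nt. In expression edgeR called 0 of 9908 genes, with 657 at an unadjusted p under 0.05 and 2 by DESeq2. Camera placed ribosomal protein genes (median -0.74, adjusted p = 1.8e-18) and collagens (-0.42, adjusted p = 2.5e-05) lower. Neither call held with an estimated correlation (adjusted p = 0.32 and 0.43). Meiotic, eggshell, poly(A) polymerase partner and oocyte lists were placed higher (medians 0.43, 0.60, 0.37 and 0.30; adjusted p = 0.00075, 0.0012, 0.003 and 0.009; adjusted p = 0.32, 0.43, 0.32 and 0.32 with an estimated correlation), with 0 members called. These medians fell to 0.27, 0.33 and 0.17 for meiotic, eggshell and oocyte genes without ccf-1 replicate 2, to 0.23 and 0.18 for partner and oocyte genes without control replicate 2, and to -0.13 for collagens without control replicate 1.

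The other RNAi labels gave few changes in tail length. In panl-2 RNAi, 46 of 6641 genes were longer and 0 shorter (27 and 0 centred). The largest were the meiotic axis gene him-3 (34.50 ± 7.16 nt), the Elongator gene elpc-2 (32.90 ± 6.88 nt) and the signal peptidase gene spcs-1 (30.61 ± 5.32 nt). These calls were lost without control replicate 2 or either panl-2 replicate (adjusted p up to 0.5), with spcs-1 at 18.3 nt without control replicate 2. With centred tail lengths him-3 and elpc-2 were not called (adjusted p = 0.07 for both). The count of 46 was 142 without control replicate 1, 1 without control replicate 2, 5 without panl-2 replicate 1 and 3 without panl-2 replicate 2. Limma called 0 genes in parn-1 RNAi (of 6698, 230 at an unadjusted p under 0.05), caf-1 RNAi (of 6687, 263) and ccr-4 RNAi (of 6698, 484). Without control replicate 1 the counts were 4, 6 and 15, and 9 for caf-1 RNAi without caf-1 replicate 1. In ccr-4 RNAi camera placed oocyte genes higher (median 2.91 nt, adjusted p = 0.008; adjusted p = 1 with an estimated correlation) and neuron genes lower (-0.05 nt, adjusted p = 0.0015; 0.073 with an estimated correlation). The neuron median was 0.64 nt without control replicate 1 and 0.86 nt without ccr-4 replicate 2, but -0.32 without control replicate 2 and -0.82 without ccr-4 replicate 1.

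In expression edgeR called 0 of 9908 genes for parn-1, caf-1, panl-2 and ccr-4 RNAi, with 124, 228, 1582 and 258 at an unadjusted p under 0.05, and DESeq2 called 1, 0, 177 and 1. Without single libraries edgeR called 5 genes (caf-1 RNAi, without caf-1 replicate 1), 2 (panl-2 RNAi, without panl-2 replicate 1) and 200 (panl-2 RNAi, without panl-2 replicate 2). Camera placed sperm genes lower in caf-1 RNAi (median -0.48, adjusted p = 0.024; adjusted p = 0.95 with an estimated correlation) and higher in ccr-4 RNAi (0.87, adjusted p = 3.1e-06; adjusted p = 0.66 with an estimated correlation), with 0 members called. The sperm median in caf-1 RNAi was -1.51 without caf-1 replicate 1 and 0.16 without caf-1 replicate 2, and in ccr-4 RNAi it was 0.39 without ccr-4 replicate 1. No list was called for parn-1 or panl-2 RNAi.

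The genes that were shorter in gld-2 than N2 in run 1, here called GLD-2-dependent, were then followed in the RNAi libraries of run 2. In ccf-1 RNAi 544 of 871 measured members were longer and 0 shorter, and 98.2% had a positive change. On centred tail lengths 8 were longer, 85.3% had a positive change, and the medians were 3.49 nt for listed and -0.75 nt for other genes. Uncentred, their median change was 8.80 nt against 4.56 nt for other genes (camera adjusted p = 3.8e-33; unadjusted p = 0.009 with an estimated correlation). In ccr-4 RNAi the medians were 2.94 and 2.17 nt (adjusted p = 8.8e-08; unadjusted p = 0.24 with an estimated correlation), and 0 of 873 members were called. Differences between listed and other genes were 0.36 nt for caf-1 (adjusted p = 0.052, or 0.038 with the replicate number as a block), 0.11 nt for parn-1 (adjusted p = 0.12) and -0.13 nt for panl-2 (adjusted p = 0.27), where camera's direction for panl-2 was upward. All 3 of these differences took the other sign without single libraries: caf-1 -0.24 without caf-1 replicate 2, parn-1 -0.08 without control replicate 1 and -0.24 without parn-1 replicate 2, and panl-2 0.72 without panl-2 replicate 1. The number of members called in ccf-1 RNAi was 0 without ccf-1 replicate 2 and 23 without control replicate 2, while the difference of medians lay between 3.11 and 5.40 nt without any 1 library.

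Embryos at the 1- to 2-cell stage were compared with N2 young adults to ask which mRNAs the early embryo holds. Stage and sequencing run coincide here and cannot be told apart. Of 85 neuron genes 51 fell in embryos and 2 rose (59 and 3 adjusted over the list alone). Their median was -1.80, or -1.77 with genes at 0 counts set to their bound (camera adjusted p = 2.6e-10, adjusted p = 0.38 with an estimated correlation). The neuropeptide gene nlp-49 fell from 160 ± 3.73 to 12.5 ± 6.38 CPM (edgeR adjusted p = 7.4e-05). Of 25 muscle genes 21 fell and 1 rose (22 and 1 adjusted over the list alone), with a median of -1.24 (camera adjusted p = 5e-06, adjusted p = 0.38 with an estimated correlation). Examples are unc-52, perlecan (75.2 ± 4.15 to 14.5 ± 2.88 CPM) and myo-2, pharyngeal myosin (47.3 ± 4.75 to 4.95 ± 2.96 CPM). The somatic lists did not all fall in this way. Medians were -0.1 for 82 collagen genes and 0.4 for 31 intestine genes. Of counts outside ribosomal RNA, vitellogenins took 2.46% in embryos and 3.18% in N2, and collagens 3.61% and 6.64%. Whether all reads of the embryo libraries are embryonic mRNA is open. Oocyte and maternal genes rose in 15 of 25 cases and fell in 3 (17 and 3 adjusted over the list alone; median 0.49, camera adjusted p = 0.00085, adjusted p = 0.38 with an estimated correlation). Genes of polarity and division rose in 14 of 38 and fell in 2 (15 and 2 adjusted over the list alone; median 0.40, camera adjusted p = 0.0025, adjusted p = 0.38 with an estimated correlation). The mitotic kinase cdk-1 rose from 276 ± 18.7 to 507 ± 6.09 CPM and the PUF-family gene puf-6 from 102 ± 12.3 to 239 ± 56.1 CPM. The oocyte yolk receptor rme-2 fell from 281 ± 0.528 to 143 ± 18.7 CPM. Early zygotic genes fell in 6 of 14 cases and rose in 1 (median -1.61, or -1.54 with genes at 0 counts at their bound, camera adjusted p = 0.018, adjusted p = 0.38 with an estimated correlation). Without N2 replicate 1, 2 or 3 the neuron genes down were 30, 27 and 30 and the early zygotic genes down 2, 1 and 2. The oocyte genes up were 8 without N2 replicate 2 or 3, as were those of polarity and division, and the neuron median was -3.03 without embryo replicate 1.

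Over 9343 genes edgeR called 1506 higher and 1709 lower (DESeq2 3190 in all). The highest ratio of reads to N2 was that of ccr-4 (308 ± 251 against 2.72 ± 0.63 CPM), followed by the metallothionein mtl-1 (log2 change 4.84 ± 0.54), ech-9 (4.57 ± 0.47), the parkin homologue pdr-1 (3.66 ± 0.18) and gda-1 (3.48 ± 0.16). The largest decreases were phat-7 (-4.10 ± 0.28), fipr-2 (-4.01), msra-1 (-3.94), nlp-13 (-3.89) and nlp-49 (-3.68). The ccr-4 reads of the embryos had tails of 14.5 ± 1.32 nt against 40.7 ± 5.85 in N2, and ccr-4 was at 979 ± 110 CPM in the libraries labelled ccr-4 RNAi of the same run. Whether the ccr-4 reads of the embryos are embryonic mRNA or come from another library of the run is open, so neither its count nor its tail length is read here as a change in embryos. Without embryo replicate 1 the log2 change of fipr-2 was -6.36. Subtraction of the run difference of gld-2 worms left 1413 genes called. The step also subtracted any effect of RNAi food or culture, and the labels give RNAi food for neither embryos nor N2. It kept the calls of unc-52 (-1.61), myo-2, nlp-49 (-1.91), fipr-2 (-2.34), cdk-1, puf-6 and phat-7, and ended those of mtl-1 (0.69), pdr-1 (0.26), gda-1 (0.30) and rme-2 (-0.20), while ccr-4 was at 3.52. Of 49 named calls in expression or tails of embryos it kept 16, ended 30 and reversed 3. The step also brings in the spread of the gld-2 groups, and their food or culture may have ended calls too. An ended call alone thus does not show that the run made the change. Most named embryo changes stay unseparated from the run. The count of 3215 was 1910, 1548 and 1541 without N2 replicate 1, 2 and 3.

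Tail lengths of single maternal mRNAs went both ways in the embryos. The cyclin B gene cyb-3 was longer, at 51.4 ± 0.282 against 38 ± 1.3 nt (13.42 ± 0.97, limma adjusted p = 0.0032), as was pos-1, at 45.2 ± 1.69 against 36.5 ± 1.04 nt. The tail of puf-3 was shorter, at 29 ± 0.0896 against 39.1 ± 1.46 nt (adjusted p = 0.0095). Of 25 oocyte and maternal genes 3 were shorter and 1 longer (6 and 1 adjusted over the list alone; median -2.94 nt, camera adjusted p = 0.037, adjusted p = 0.78 with an estimated correlation). Of 37 genes of polarity and division 4 were longer and 1 shorter (4 and 3 adjusted over the list alone), with a median of -1.56 nt and a mean of 0.04 (camera direction upward with adjusted p = 0.82). Of 5 vitellogenins 3 were shorter (4 adjusted over the list alone; median -4.93 nt, camera adjusted p = 0.002, adjusted p = 0.42 with an estimated correlation), with vit-6 at 37.8 ± 2.2 against 45.9 ± 2.09 nt. Without N2 replicate 1 or 3, 0 vitellogenins were called, and without N2 replicate 1, 0 oocyte genes. Whether the vitellogenin reads of these libraries are embryonic mRNA is open.

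Over 6442 genes limma called 186 longer and 220 shorter (339 and 199 centred). The largest increases were hlh-3 (44.21 nt), cup-16 (42.05 nt), ttc-36 (41.65 nt), pgrn-1 (38.2 nt) and pnk-4 (35.82 nt). The largest decreases were nspd-2 (-30.36 nt), faah-2 (-29.41 nt), ccr-4 (-26.18 nt, of reads of open origin), noah-1 (-20.77 nt) and lsy-13 (IV: 16863842 to 16865292; -20.13 ± 1.94 nt). Of the genes named here, lsy-13 and cyb-3 kept their calls without any single library (highest adjusted p 0.047 and 0.024). By contrast puf-3 lost its call without N2 replicate 1 (adjusted p = 0.058), vit-6 and ccr-4 without N2 replicate 1 or 3, ttc-36 without N2 replicate 1 or 2, and the others without N2 replicate 1, 2 or 3. The change of pnk-4 was 23.01 nt without embryo replicate 1 and that of ttc-36 25.26 nt without embryo replicate 2. The count of 406 was 10, 28 and 18 without N2 replicate 1, 2 and 3, 2418 and 2344 without embryo replicate 1 and 2. After the run difference was subtracted it was 0, and neither cyb-3 nor lsy-13 was called. Changes were then 38.3 nt for ttc-36, 43.95 nt for pnk-4, -35.93 nt for faah-2 and -8.18 nt for lsy-13. Calls were thus lost both where the size fell strongly (lsy-13) and where it did not.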

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

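Fits without ribosomal RNA rows, on one-gene rows only and without cpb-3 replicate 3 beside another choice were chosen after the data were seen; the other alternatives were fixed before. Of 217 alternative counts of changed genes, 164 stayed within 1.5 times the reported count. The 164 include comparisons in which neither fit called a gene, so they do not show how stable the remaining counts were. Of the alternatives of single lists, 774 kept their state, called or not called, which includes lists called in neither fit. Another 84 lost the call, 16 gained it and 2 reversed. Of 77 list calls an estimated correlation kept 5 and the replicate block 73, and centred tail lengths kept 27 of 36. Of those of named genes, 3701 kept their state, genes called in neither fit included. Another 249 lost the call, 46 gained it and 3 reversed. With DESeq2, RLE size factors, no count filter or no ribosomal RNA rows, each of 124 named expression calls was kept. Where a result changed, the cause was not tested, except that a fit without 1 library has fewer samples.

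Counts of genes changed in expression moved as follows. For cpb-3 vs N2 (909) a fit of only these 2 groups gave 455. For the RNAi labels (0 in edgeR), no count filter and DESeq2 gave 2 and 1 for parn-1, 320 and 177 for panl-2, 19 and 2 for ccf-1, and 8 and 1 for ccr-4. For embryos (3215), subtraction of the run effect gave 1413. With each library left out in turn the counts ran from 380 to 1335 for cpb-3 vs N2, 0 to 5 for caf-1 RNAi, 0 to 200 for panl-2 RNAi and 1541 to 4454 for embryos.

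Counts of genes changed in tail length moved more often. With centred tail lengths they were 70 for cpb-3 vs N2 (0), or 95 without cpb-3 replicate 3 as well, 27 for panl-2 RNAi (46) and 15 for ccf-1 RNAi (1345). For panl-2 RNAi a mean of 5 tailed reads, with single values from 1 read, gave 16, weights by tailed reads 23, and only the 2 groups 18. For embryos (406) a mean of 5 tailed reads gave 245 and subtraction of the run effect 0. With each library left out in turn, counts ran from 461 to 1158 for gld-2 vs N2 (905), 0 to 4 for cpb-3 vs N2 and 837 to 2165 for gld-2 vs cpb-3 (1543). Those of the RNAi labels ran from 0 to 4 for parn-1, 0 to 9 for caf-1, 1 to 142 for panl-2, 0 to 1024 for ccf-1 and 0 to 15 for ccr-4, and those of embryos from 10 to 2418.

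The labels do not say that a replicate number marks a shared batch or day, so the samples share only a number and no pairing was used. Deviations of same-numbered libraries correlated at -0.19 to 0.20 in run 1 expression (2 of 9 over 0.1) and at -0.15 to 0.39 in run 2 expression (22 of 30 over 0.1), and at -0.02 to 0.12 in run 2 tails. With 2 libraries per group the deviations in run 2 are equal and opposite. Each pair of groups therefore gives the same value for both replicate numbers, and the 30 are not separate values. In the 6 RNAi groups replicate 1 had the higher share of innate immunity genes in 6 and the higher collagen share and median tail in 5 each, so a batch that follows the numbers in run 2 may exist and is left open. With the replicate number as a block, the counts were 1700 for embryos in expression, 111 for panl-2 RNAi in tail length and 67 for embryos in tail length, and the other counts stayed within 1.5 times. The difference of GLD-2-dependent genes in caf-1 RNAi, 0.36 nt, had an adjusted p of 0.038 with the block and 0.052 without. Of 77 list calls the block kept 73 and added 6, and, of the named calls it covers, it kept 190 and lost 20.

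The difference in tail change between GLD-2-dependent and other genes was also taken with a list from gld-2 vs cpb-3. It was then 0.30 nt for parn-1 (0.11), 0.40 nt for caf-1 (0.36) and 0.22 nt for panl-2 (-0.13, a reversal). For ccr-4 it was 1.24 nt (0.78) and for ccf-1 4.36 nt (4.24). With centred tail lengths it was 0.36 nt for caf-1 and its unadjusted camera p no longer passed, as with an estimated correlation (0.36 nt), which also ended the call for ccr-4 (0.78 nt). With each library left out in turn it ran from -0.24 to 1.18 nt for caf-1, -0.24 to 0.33 nt for parn-1 and -1.01 to 0.72 nt for panl-2, each through 0.

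An estimated inter-gene correlation left 5 of 77 list calls. Centred tail lengths reversed the median of ribosomal protein genes to 0.22 nt in gld-2 vs N2 (-2.50) and to -1.34 nt in ccf-1 RNAi (3.97), and they gave 3 genes longer and 7 shorter in both mutants (0 and 0). Subtraction of the run effect in embryos reversed puf-5 to -0.19 (1.16), tbx-9 to -0.30 (0.97) and the tail of vit-4 to 1.20 nt (-8.09). With means weighted by tailed reads, the difference of library medians between cpb-3 and N2 was -0.93 nt (0.98).

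Small changes were found less often in data simulated from run 2. Only genes of higher counts were changed in the simulations. A change of 1 on the log2 scale was found in 8% of cases for ccf-1 RNAi and 67% for gld-2 vs N2, and a tail change of 10 nt in 34% and 58%. Number of libraries, spread and depth differ together between these 2 comparisons, and the part of depth was not tested.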

Other observations

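The 2 tests of the shorter tails in gld-2, the test of a shared shift in ccf-1 RNAi and both tests of the sperm genes were chosen after those results were seen; the other tests were set before. Across 6442 genes of the embryo comparison, which are not independent replicates, tail change and expression change had Pearson r = -0.19, and 82 genes were shorter and higher, where independent lists would share 45.1. In gld-2 vs cpb-3, 392 genes were shorter and lower (313 for independent lists).

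Shorter tails in gld-2 than in N2 were set against a loss of cells that hold the long-tailed copies and against a shift shared by all genes of a library. Of the 891 genes called shorter, 44% had a log2 expression change under -0.25, against 33.7% of other genes, and 553 were not called in expression. These values argue only against a loss of such cells without replacement as the whole cause. Counts would stay level if other cells hold short-tailed copies of the same mRNAs, so a changed make-up of cells is left open. The sperm list took 0.0206% of counts outside ribosomal RNA in N2 and 0.543% in gld-2. The 589 genes called shorter on centred tail lengths argue against a shared shift as the whole cause. A direct effect of GLD-2 on these mRNAs stays a hypothesis, since worms may also differ in the stage of their oocytes, which was not tested.

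Longer tails of GLD-2-dependent genes in libraries labelled ccf-1 RNAi were set against 3 technical explanations. A shift shared by all genes would leave no difference between listed and other genes, and the lowest difference with each library left out was 3.11 nt. Unlisted genes matched in starting tail length (31.4 nt in both) and depth changed by 5.12 nt against 8.80 nt. The difference was 3.68 nt (3.38 to 3.92 over resampled genes, which leaves out the spread between libraries). In these libraries starting length and depth thus do not account for the whole. The matching did not use tissue. Oocyte and maternal genes lengthened in this comparison while neuron and muscle genes did not. The difference may therefore be one of germline against somatic genes, which was not tested. Among genes with a log2 expression estimate under 0 the difference was 4.86 nt (8.89 nt in 425 listed and 4.04 nt in 2948 other genes), but 0 genes were called in expression, so an increase of cells with long-tailed copies is left open. An effect of ccf-1 RNAi on these tails may be the source, but reads of the ccf-1 gene itself were not lower past the test, and 2 libraries per group carry the result.

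Sperm genes were higher in both mutants of run 1 than in N2. If cpb-3 worms were younger than N2 worms, early zygotic and vitellogenin genes would be lower, but the lower of their median log2 changes was 0.21 (vitellogenins 1.14, or 0.68 without cpb-3 replicate 3), and that of early zygotic genes ran from 0.01 to 0.28 with each library left out. In gld-2 worms of run 2 on control RNAi the share of counts on the sperm list was 8.97% of that in gld-2 worms of run 1, as an origin in the age, culture or run of the run 1 worms would give. Run 2 holds no N2 adults, so the change from N2 to gld-2 in that run is not known. The run 2 share of 0.0487% still lay above the 0.0206% of N2 in run 1. How much of the gld-2 increase that explanation covers is therefore open, and run, food and culture cannot be told apart here.

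Other splits of the 6 libraries of 2 groups were counted for each comparison of run 1. There are 10 splits into 3 and 3, too few for a share under 0.05. For expression the real split gave 2948 genes in gld-2 vs N2, 909 in cpb-3 vs N2 and 3766 in gld-2 vs cpb-3, and the highest other split 0 in each, so 1 of 10 splits gave as many. For tail lengths the real split gave 905 genes in gld-2 vs N2 and 1543 in gld-2 vs cpb-3 (highest other 0, 1 of 10 splits), and 0 in cpb-3 vs N2, where 10 of 10 splits gave as many (highest other 0).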
